A study of Oryza sativa with 6 samples.

How the data were processed

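Messenger RNA was sequenced from the roots of the rice cultivar IR29, which the series describes as sensitive to salinity. The labels place 1 library in each of 6 groups, made from 3 root types under control conditions or after 7 days of 50 mM NaCl. Per the labels' protocols, plants grew at 30 °C by day and 25 °C by night, RNA was taken up with a column kit, and the libraries kept strand information with inserts of 200 bp. No label gives a replicate, a batch or a sequencing date.

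Per the submitters' processing notes, the tools were Trimmomatic 0.32, Bowtie, TopHat2 2.0.11, Cufflinks 2.2.1 and Cuffdiff 2.2.1, and the genome build was IRGSP-1.0. The authors deposited a signal per locus and library, which is a number of reads divided by 1 size factor per library. It lists 37938 loci, of which 828 carry no gene ID and 325 gene IDs stand on more than 1 locus; loci without an ID held at most 0.58% of a library's reads. The authors also deposited FPKM values (fragments scaled by transcript length and library depth) with p-values and q-values for 15 pairwise comparisons of the 6 groups; the layout of that table, per the file headers, is that of Cuffdiff. Its column of log2 folds holds 31741 cells that are not numbers, so that column was not used here. How the authors' counting treated reads shared by near-identical copies is not given in the sources used here, so single members of gene families are uncertain.

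Division of each library's signal by its smallest step gave whole numbers, within 0.01, for 99.897% to 99.977% of the values above 0, and these whole numbers are called reads. The totals were 4249872, 4081780 and 3889244 reads in the control nodal, S-type and L-type libraries, and 4126193, 3895211 and 3839177 in the salt libraries. Reads were scaled with TMM factors to a mean library of 3998627 reads. The TMM factors were 1.064 (nodal), 0.825 (S-type) and 1.17 (L-type) under control and 1.116, 0.798 and 1.094 under salt.

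Because the deposited unit is a scaled signal and not raw counts, the test across libraries was limma-trend 3.58.1 (R 4.3.3) on log2(scaled reads + 1), which had been set as the fallback, in place of the quasi-likelihood count test set down first. One additive model of root type and treatment was fitted to all 6 libraries for the 19469 loci with at least 10 reads in at least 2 libraries. Its 2 residual degrees of freedom come from the interaction of root type and treatment, so its p-values measure how evenly a difference repeats over treatments or root types, not the spread between plants. Benjamini-Hochberg adjustment at 0.05 was applied over all loci, two-sided. Fold changes are on the log2(scaled reads + 1) scale, which understates the change of loci with few reads. The count test, edgeR 4.0.16 on the recovered reads, was run as an added alternative, and the DESeq2 1.42.0 Wald test as a planned one.

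Comparisons of 1 library with 1 library have no test. A locus was counted as higher or lower by a rule of size: a change of at least 2-fold on the log2(scaled reads + 1) scale, at least 50 scaled reads in the higher library, and a 95% exact conditional binomial (Clopper-Pearson) interval of the ratio that excludes 1. That interval, like the floor of 3 reads per library used where a library had 0 reads, covers counting error only, and reads made by PCR without molecular identifiers are not independent molecules. Folds against 0 reads are taken against that floor, and the lower end of the two-sided interval lies below them, as 77.04 against 95.4 for Os03g0184100. Correlations of salt changes used the 12229 loci with a mean of at least 50 scaled reads. They run across loci, which are not independent replicates, so no p is given.

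The rule for naming loci was set before the data were examined, as were the tests, most processing alternatives and 26 gene lists. For a fit, the rule took the 10 higher and 10 lower loci with the largest fold among those past the threshold that kept their direction in each treatment or root type, with a mean of at least 100 scaled reads. For 2 libraries it took the 10 higher and 10 lower loci with the largest fold among those meeting the rule of size with at least 200 scaled reads in the higher library and with a symbol or a description. For differences of salt changes it took 5 loci per direction and pair of root types. It also took list members with the largest salt changes and several ion transporters. The files do not pair gene IDs with names, and only 1 of the 36773 gene IDs matched the reference table of assembly ASM3414082v1, so no locus had a symbol or a description. Departing from the rule, a choice made after the data were seen, at most 2 loci per direction with the largest folds are printed by ID for the fits and for salt in each root type; list members and ion transporters are not named singly, and no gene symbol is given. Coordinates are those of the deposited files.

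The gene lists are groups of rice IDs written down from general knowledge of the literature; their membership was not checked against an annotation. Of the 26 lists, 7 rested on text descriptions that could not be matched and were not run (auxin response, class III peroxidases, glutathione S-transferases, cell division, defence proteins, heat shock proteins and ribosomal proteins). Expansins had 0 measured members, root hair genes 1 and fermentation genes 2, too few to describe. The other 16 lists had at least 3 members with a mean of at least 20 scaled reads. Measured were 7 of 14 IDs listed for ABA response, 6 of 13 for sodium and potassium transport and 8 of 16 for lateral and crown root development. The dehydrin and late embryogenesis abundant loci of the ABA response list had at most 6.7 scaled reads in any library and were not measured. List results describe the measured members alone. For each, the members higher or lower were counted, and the median log2 change was placed among 10000 random lists of the same size matched on mean level in 20 bins. That percentile describes these libraries and is not a test. Percentiles for root type contrasts, on the mean of the changes under both treatments, were added after the data were seen.

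The additive fit was tested on simulated data that gave every locus the same dispersion and no changes beyond those put in. Real loci differ in spread, so recovery there may be lower. A count of 0 calls in the real fit therefore does not show that large shared changes are absent. With a dispersion of 0.177, estimated from the 6 libraries, and 50 loci changed at each size, the salt contrast on 18856 loci recovered 4% of 2-fold, 42% of 4-fold, 88% of 8-fold and 90% of 16-fold changes, with 8 unchanged loci called. The contrast of S-type with nodal roots on 18876 loci recovered 2%, 12%, 78% and 92%, with 3 unchanged loci called. The rule of size was tested with counting error alone on 37938 loci: for salt in nodal roots it recovered 50.0% of 2-fold and 100% of 4-fold changes and called 0 unchanged loci, and in S-type roots it recovered 50.0% and 98.0% and called 10. The rule of size was computed with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3), and matplotlib 3.10.9 drew the plots.

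Alternatives changed the scaling (median-of-ratios factors, library totals, the authors' size factors), the test, the filter on low reads, the pseudocount, the fold and read minimum, the threshold, the use of FPKM in place of scaled reads with 0.1 added, the depth, and the libraries in the fit. The added ones were the authors' size factors, thinning to the shallowest library, a pseudocount of 10 in the fit, and list medians under median-of-ratios or the authors' factors. The edgeR test, set down first as the main test, was also added as an alternative.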

Results

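Gene expression was measured in 3 kinds of rice root with and without salt. Nodal roots are the shoot-borne main axes of the rice root system, and lateral roots branch from them as short S-type or longer L-type laterals. The series set out to find genes that act in lateral roots under salinity. Each of the 6 libraries held between 3839177 and 4249872 reads on loci, and between 21368 and 24121 loci had at least 1 read. Each group was 1 library, so there is no spread between replicates anywhere in these data: the fits across libraries are the only tests, and comparisons of 2 libraries describe those libraries, with counting error alone. Gene groups are lists of IDs set down before the data were examined from general knowledge; their membership was not checked against an annotation.

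Nodal and S-type libraries stood farther from each other than from the other library of their own root type, while L-type libraries stood between them. On the first principal component, which held 60.7% of the variance of log2 scaled reads, the nodal libraries lay at -121.3 (control) and -105.2 (salt), the L-type libraries at -23.2 and -1.6, and the S-type libraries at 80.0 and 171.4. Across 15997 loci, the control and salt libraries of 1 root type correlated at 0.83 in nodal, 0.866 in S-type and 0.798 in L-type roots. Nodal and S-type libraries correlated at 0.579 under control and 0.425 under salt. The control L-type library stood closer to the control nodal (0.744) and control S-type (0.733) libraries than these stood to each other. The salt L-type library correlated at 0.787 with salt nodal, at 0.736 with salt S-type and at 0.799 with control S-type roots, about as closely as with control L-type roots.

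The first comparison asks which genes distinguish S-type lateral from nodal roots whatever the treatment. The medians of the lists for jasmonate synthesis and signalling, abscisic acid (ABA) response and stress transcription factors were above 0 in S-type against nodal roots, and those for aquaporins (water channels) and the secondary cell wall were below 0; not every member passed the threshold. Of the 8 measured jasmonate loci, 5 were higher at an adjusted threshold of 0.05 over all loci and 7 adjusted over the list alone, and their median log2 difference was 4.10 (percentile 100 of matched random lists). Of the 7 measured ABA response loci, out of 14 listed, 5 were higher and 1 lower, the same numbers adjusted over the list alone. Their median was 2.15 (percentile 99.52), and the dehydrin and late embryogenesis abundant loci of that list were not measured. Of the 5 stress transcription factors 3 were higher by both counts (median 2.27, percentile 97.91), and of the 3 ABA synthesis and breakdown loci 2 were higher by both counts (median 3.33, percentile 99.17). Aquaporins had 5 of 12 loci lower, 7 adjusted over the list alone, with a median of -2.24 (percentile 0.0). All 3 measured secondary wall loci were lower by both counts, with a median of -6.41 (percentile 0.0): together they had 4107.7 scaled reads in the control nodal library, 114.4 in control S-type and 7.7 in salt S-type roots. Lateral and crown root development loci had 2 of 8 lower by both counts (median -1.35, percentile 0.38).

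Among the remaining lists, sodium and potassium transport had 0 higher and 2 of 6 lower over all loci, and 1 higher and 2 lower adjusted over the list alone; its median of 0.60 turned negative, -0.26, when libraries were scaled by their totals. Among 3 osmolyte synthesis loci 1 was higher and 1 lower, and among 5 iron and metal uptake loci 1 was higher and 1 lower, each by both counts. The list for the Casparian strip and suberin, of which 1 measured locus was listed for the strip and 2 as silicon transporters, had 1 of 3 higher and 2 adjusted over the list alone. By both counts, 1 of 5 cytokinin response loci, 1 of 4 antioxidant enzymes and 1 of 4 reference genes were lower. The reference genes, often used to scale such data, had a median of -1.06 (percentile 2.53). None of the 4 nitrate and ammonium transport loci and none of the 4 photosynthesis loci passed either threshold. The photosynthesis median was -3.18 (percentile 0.2), and it rested mainly on the salt nodal library. Summed scaled reads were 35.5 in nodal and 17.9 in S-type roots under control, and 1942.3 and 25.8 under salt.

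Across both treatments, limma called 2199 loci higher and 1506 lower in S-type than in nodal roots, out of 19469 (7180 at an unadjusted p under 0.05). The edgeR test called 1741 higher and 835 lower, and DESeq2 2549 higher and 2191 lower. The largest fitted difference upward was at Os11g0428800 (chromosome 11, 13723176 to 13724624), with 7954 and 31214 scaled reads in control and salt S-type roots against 3 reads in each nodal library; the ratio was 2987 under control (95% counting interval 1022 to 14490), and the fitted log2 difference was 12.08 ± 0.55 (SE, limma adjusted p = 0.00499). Os02g0584200 (chromosome 2, 22509549 to 22531379) had 1474 and 1964 scaled reads in S-type roots against 3 reads and 0 in nodal roots. The ratio was 553.4 under control (95% counting interval 188.9 to 2687), and it was at least 749.5-fold higher under salt (limma adjusted p = 0.00514). In the other direction, Os03g0103200 (chromosome 3, 208339 to 211818) had 9994 and 6847 scaled reads in nodal roots and 7.1 and 0 in S-type roots, at least 1770-fold lower under salt. Os01g0881300 (chromosome 1, 38254052 to 38257621) had 1043 and 1490 scaled reads in nodal roots and 0 in both S-type libraries, at least 291.8-fold lower under control and at least 385.2-fold lower under salt. Both had a limma adjusted p of 0.00499. The total of 3705 loci depended on which libraries were in the fit, and leaving out 1 library moved it in both directions. Such a fit takes its treatment effect and its error only from the 2 root types that keep both libraries. It therefore cannot show that the calls rest on the library left out. Scaling by library totals turned the split from 59.4% to 38.4% higher.

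Within 1 treatment, S-type roots had 3668 loci higher and 2638 lower than nodal roots under control, and 3374 higher and 3103 lower under salt. Scaling by library totals turned the share higher from 58.2% to 41.5% under control and from 52.1% to 33.6% under salt, where a minimum of 10 scaled reads gave 44.6% and 4-fold gave 1856 higher and 1859 lower. Across 12229 loci the 2 sets of differences correlated at 0.779. They shared 2227 higher loci, where independent lists would share 757.9, and 1332 lower loci, where independent lists would share 387.2; 127 loci went opposite ways.

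**Figure D1:**
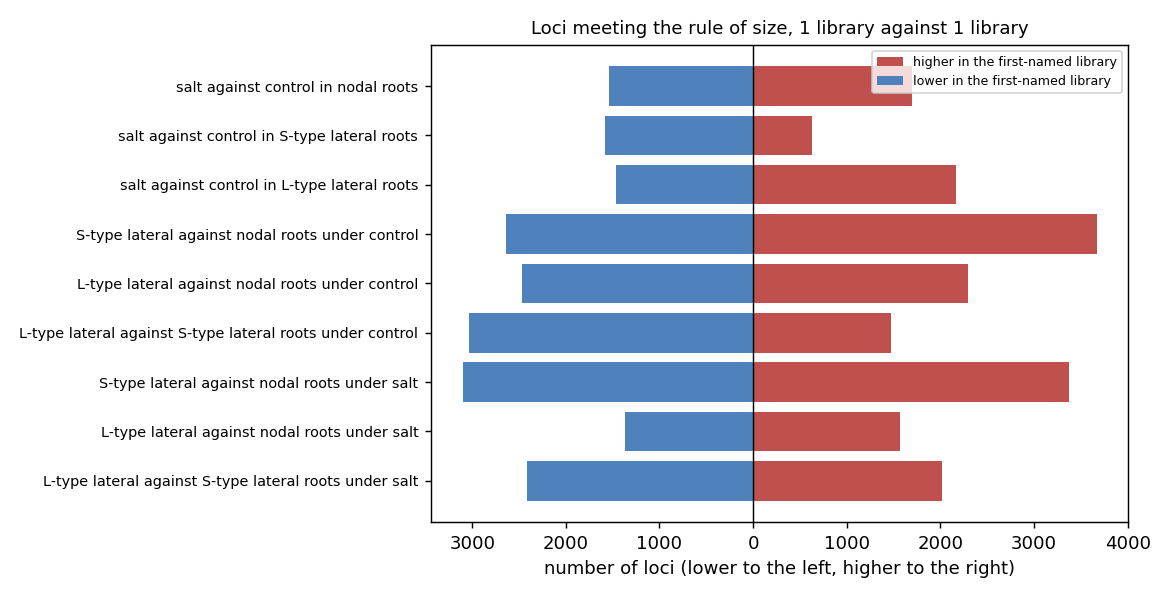
Number of loci that met the rule of size in each comparison of 1 library with 1 library; red bars to the right are loci higher in the first-named condition and blue bars to the left are loci lower. S-type against nodal roots gave the largest totals, with 6306 loci under control and 6477 under salt, and salt in S-type roots the smallest, with 624 higher and 1581 lower.

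L-type lateral roots differed from nodal roots in several of the same gene groups, with smaller medians. The median log2 difference was 2.19 (percentile 100) for the jasmonate list, 1.97 (percentile 100) for ABA response, -1.66 (percentile 0.0) for aquaporins and -4.43 (percentile 0.0) for secondary wall loci. No locus in any list passed the threshold over all loci. Adjusted over the list alone, 6 of 8 jasmonate, 4 of 7 ABA response and 2 of 3 ABA synthesis and breakdown loci were higher. In the same way 6 of 12 aquaporins, 3 of 3 secondary wall, 2 of 5 iron uptake and 2 of 4 reference loci were lower. Medians were not smaller in every list. The reference genes had a median of -1.135 (percentile 0.97), against -1.057 in S-type against nodal roots. Iron and metal uptake had -1.819 (percentile 0.03), against 1.007 there. Sodium and potassium transport, cytokinin response and antioxidant enzymes had 1 locus lower each and osmolyte synthesis 1 higher and 1 lower, also adjusted over the list alone. Lateral and crown root development had a median of -0.94 (percentile 0.18) with 0 loci past either threshold, and stress transcription factors a median of 1.65 (percentile 99.5) with 0 of 5 past either.

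The limma fit called 0 loci between L-type and nodal roots (3201 at an unadjusted p under 0.05), edgeR called 0 and DESeq2 called 995. Leaving out 1 S-type library gave 1870 (control) or 1877 (salt) calls. By the rule of size, 2298 loci were higher and 2465 lower in L-type than in nodal roots under control, and 1564 higher and 1371 lower under salt. Under control the share higher was 48.2%, and scaling by library totals turned it to 56.8%. These 2 sets of differences correlated at 0.615 across loci and shared 712 higher loci (229.4 for independent lists) and 665 lower loci (155.4 for independent lists), with 59 opposite.

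Between the 2 kinds of lateral root, iron and metal uptake loci were lower in L-type than in S-type roots. All 5 were lower adjusted over the list alone and 0 over all loci, with a median log2 difference of -1.63 (percentile 0.96). The jasmonate list had 4 loci lower and 1 higher adjusted over the list alone (median -1.46, percentile 0.54), and the ABA response list 3 lower and 1 higher (median -0.64, percentile 7.49). Among its 4 members with a mean of at least 100 scaled reads, the ABA response list had a median of -1.23 (percentile 2.39). ABA synthesis and breakdown had 2 lower and 1 higher, and stress transcription factors, Casparian strip and nitrate transport 2, 2 and 1 lower, adjusted over the list alone. Higher by that count were 2 sodium and potassium transport loci and 1 each of the aquaporin, secondary wall and antioxidant lists. The aquaporin median was 0.78 (percentile 99.96) and the secondary wall median 2.38 (percentile 99.91), or 1.85 with libraries at 0 reads set to the floor of 3 reads. Photosynthesis had a median of 2.96 (percentile 99.97), which rested mainly on the salt L-type library. Its summed scaled reads were 53.8 in L-type and 17.9 in S-type roots under control, and 766.7 and 25.8 under salt. In photosynthesis, lateral and crown root development, cytokinin response, osmolyte synthesis and reference genes, 0 loci passed either threshold.

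Only 2 loci passed the limma threshold in this contrast, both higher in L-type roots. Os05g0111300 (chromosome 5, 605867 to 606764) had 1.2 and 1.3 scaled reads in S-type and 597.8 and 1051.5 in L-type roots under control and salt; under control, where 1 read stood against 678, the ratio was 501.8 (95% counting interval 89.76 to 19850) and the fitted log2 difference was 8.47 ± 0.41 (SE, limma adjusted p = 0.0253). Os01g0588100 (chromosome 1, 22905454 to 22908098) differed by 5.25 ± 0.31 on the log2 scale (SE, limma adjusted p = 0.0409), and it is the 1 locus that the authors' deposited table marks as failed in their estimation. Without the control nodal, control L-type or salt L-type library 0 loci passed, without control S-type 2924 did and without salt S-type 1100. DESeq2 called 1692 and edgeR 0. By the rule of size 1475 loci were higher and 3038 lower in L-type than in S-type roots under control, and 2022 higher and 2418 lower under salt. Scaling by library totals turned the share higher from 32.7% to 64.6% under control and from 45.5% to 71.1% under salt, where a minimum of 10 scaled reads gave 57.3% and 4-fold 56.8%. The median log2 difference of all loci moved from -0.12 to 0.45 under control with that scaling.

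In nodal roots, the lists with the most members higher in the salt library were photosynthesis and stress transcription factors, and jasmonate, iron uptake, aquaporin, nitrate and ammonium, and sodium and potassium transport lists had at least 3 members lower. All 4 measured photosynthesis loci were higher, with a median log2 change of 6.11 (percentile 100), and their summed scaled reads were 35.5 in the control and 1942.3 in the salt library. Photosynthesis loci were fixed as markers of shoot tissue. Of 5 stress transcription factors 3 were higher (median 1.25, percentile 99.63) and the other 2 had changes of -0.35 and -0.66. Lower were 7 of 8 jasmonate loci (median -1.57, percentile 0.01), 4 of 5 iron and metal uptake loci (median -1.42, percentile 0.09) and 3 of 4 nitrate and ammonium transport loci (median -2.49, percentile 0.0). Sodium and potassium transport had 3 of 6 loci lower (median -1.26, percentile 0.18), but the 3 members with a mean of at least 100 scaled reads had a median of 0.34. Aquaporins had 4 of 12 lower (median -0.48, percentile 15.3).

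The other lists had percentiles between 20.54 and 90.53 in nodal roots. One locus was lower in each of osmolyte synthesis, cytokinin response, antioxidant enzymes and reference genes. In ABA response, ABA synthesis and breakdown, lateral and crown root development, secondary wall and Casparian strip, 0 met the rule. In all, 1693 loci were higher and 1535 lower (52.4% higher), a majority that turned to 43.0% with median-of-ratios factors, 44.0% with the authors' size factors, 44.4% with FPKM and 45.8% with a minimum of 200 scaled reads, while it was 56.6% with a minimum of 10, 58.6% with library totals and 70.5% at 4-fold. Among loci with at least 200 scaled reads in the higher library, the 2 largest changes upward were at neighbouring loci on chromosome 3. Os03g0826800 (34733450 to 34734892) had 35.5 scaled reads under control and 5288 under salt, a ratio of 148.9 (95% counting interval 109.2 to 208.7). Os03g0826900 (34739010 to 34740664) had 1 read under control and 341 under salt, a ratio of 335.5 (59.81 to 13290). By the same minimum, the largest changes downward were at Os02g0626600 (chromosome 2, 24992881 to 24995414), 20.3-fold lower, and Os03g0276500 (chromosome 3, 9370159 to 9373067), 13.3-fold lower.

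S-type lateral roots showed the most one-sided difference of the 3 salt comparisons, with 624 loci higher and 1581 lower in the salt library. Among the lists, aquaporins had the most members lower, 10 of 12, and 0 higher, with a median log2 change of -1.87 (percentile 0.01) and a range from -6.15 to -0.16. Their summed scaled reads were 11953.8 in the control and 4687.1 in the salt library. Iron and metal uptake loci had 4 of 5 lower (median -1.45, percentile 0.34), jasmonate 2 of 8 lower (median -0.65, percentile 2.35). Secondary wall loci had a median of -3.77 (percentile 0.05), or -2.87 with libraries at 0 reads set to the floor of 3 reads, but all lay below the minimum of 50 scaled reads, so none was counted. Lateral and crown root development had 2 of 8 lower and 1 higher (median -0.20, percentile 28.79). On the higher side, cytokinin response had 2 of 5 loci higher and all 5 above 0 (median 0.78, percentile 99.1), and ABA response had 1 of 7 higher and 6 above 0 (median 0.61, percentile 99.35), a median of 0.45 (percentile 96.07) among members with at least 100 scaled reads.

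Photosynthesis loci, by contrast with nodal roots, had 0 of 4 higher in S-type roots (median 0.25, percentile 83.13) and 25.8 summed scaled reads under salt. Stress transcription factors had 1 of 5 lower (median -0.38, percentile 16.04). Casparian strip and suberin had 1 higher and 1 lower of 3, the locus listed for the strip being the lower one (median 0.75, percentile 97.52). ABA synthesis and breakdown had 1 of 3 higher (median 0.71, percentile 97.22), a locus listed for breakdown. Nitrate and ammonium transport had 1 higher and 1 lower of 4, and 1 locus was lower in each of sodium and potassium transport and reference genes. Osmolyte synthesis and antioxidant enzymes had 0. Among loci with at least 200 scaled reads in the higher library, the largest changes upward were at Os09g0489200 (chromosome 9, 18863139 to 18867497), with a ratio of 7.26 (95% counting interval 4.825 to 11.31), and at Os01g0102900 (chromosome 1, 163367 to 170659), with a ratio of 7.09 (5.026 to 10.26). By the same minimum, the largest downward were at Os10g0552800 (chromosome 10, 21697076 to 21697778), with 348 reads under control and 1 under salt, and Os02g0662000 (chromosome 2, 26804987 to 26805820), with 193 and 1. Their ratios of salt to control were 0.00311 (95% counting interval 7.851e-05 to 0.01744) and 0.00561 (0.0001412 to 0.03162).

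In L-type lateral roots, salt went with more loci higher (2166) than lower (1465). Photosynthesis loci were higher in 4 of 4 (median log2 change 3.66, percentile 100), from 53.8 summed scaled reads under control to 766.7 under salt. Lateral and crown root development had 4 of 8 loci higher and 0 lower, with a median of 1.02 (percentile 99.02), or 0.88 (percentile 96.5) among members with a mean of at least 100 scaled reads. ABA synthesis and breakdown had 2 of 3 higher (median 1.79, percentile 99.05). Both were listed for breakdown, and the locus listed for synthesis changed by 0.38. Stress transcription factors had 2 of 5 higher (median 0.67, percentile 91.97). Iron and metal uptake had 3 loci lower and 2 higher of 5 (median -2.64, percentile 0.0). Jasmonate had 3 lower and 1 higher of 8 (median -0.64, percentile 2.78), and aquaporins 3 lower and 1 higher of 12 (median -0.54, percentile 2.78).

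ABA response in L-type roots had 2 higher and 1 lower of 7, secondary wall 1 higher and 1 lower of 3, and Casparian strip and suberin 1 of 3 higher. Antioxidant enzymes had 1 of 4 higher and osmolyte synthesis 1 of 3 lower. None met the rule among sodium and potassium transport, cytokinin response, nitrate and ammonium transport and reference genes. Os03g0184100 (chromosome 3, 4416653 to 4419091) had 0 reads under control and 264 under salt, at least 95.4-fold higher. Os06g0255400 (chromosome 6, 8069203 to 8069983) had 6 reads and 725, a ratio of 131.0 (95% counting interval 59.89 to 358.1). On the lower side, Os01g0322700 (chromosome 1, 12301585 to 12302618) was 46.5-fold and Os06g0268600 (chromosome 6, 8939331 to 8948565) 24.8-fold lower under salt.

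**Figure D2:**
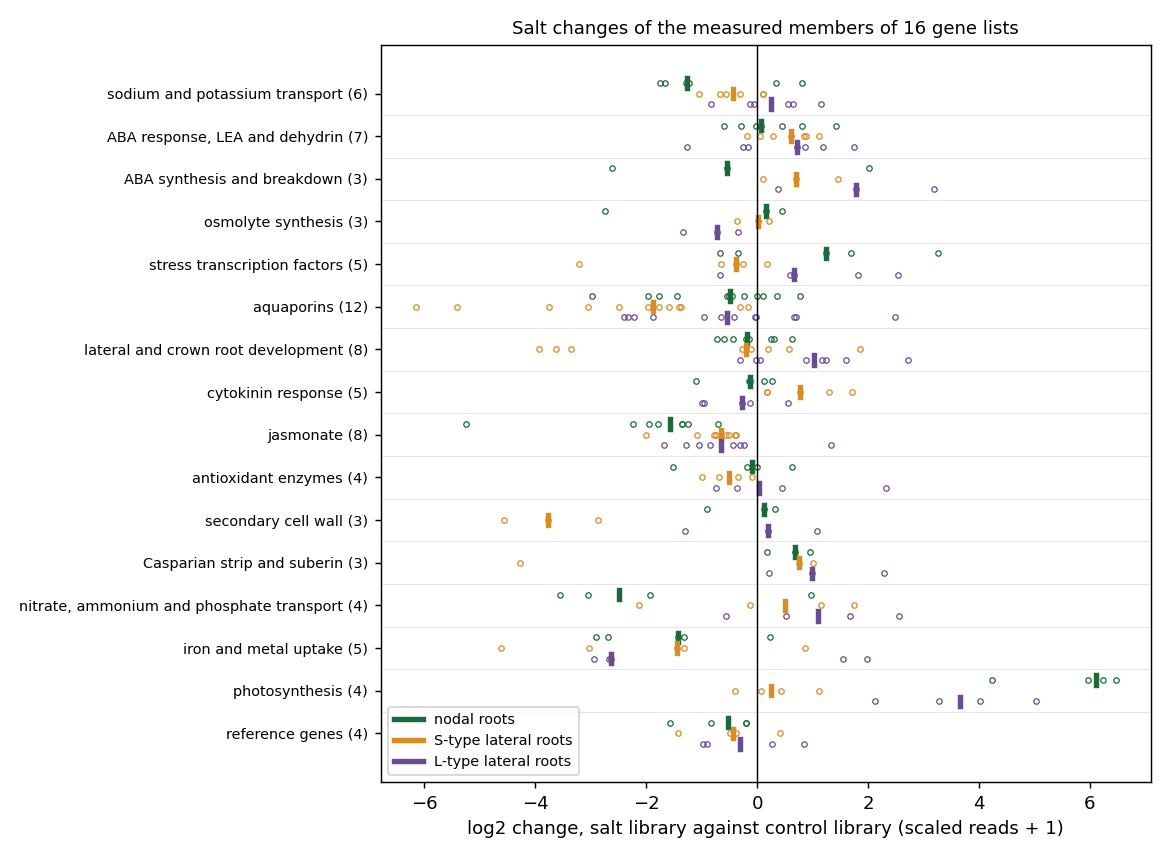
Log2 change of each measured member (open circle) and the median (thick bar) of 16 gene lists, salt library against control library, in nodal (green), S-type lateral (orange) and L-type lateral (purple) roots; the number of members is in parentheses. Photosynthesis loci had medians of 6.11 in nodal, 0.25 in S-type and 3.66 in L-type roots, and aquaporins -0.48, -1.87 and -0.54.

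**Figure D3:**
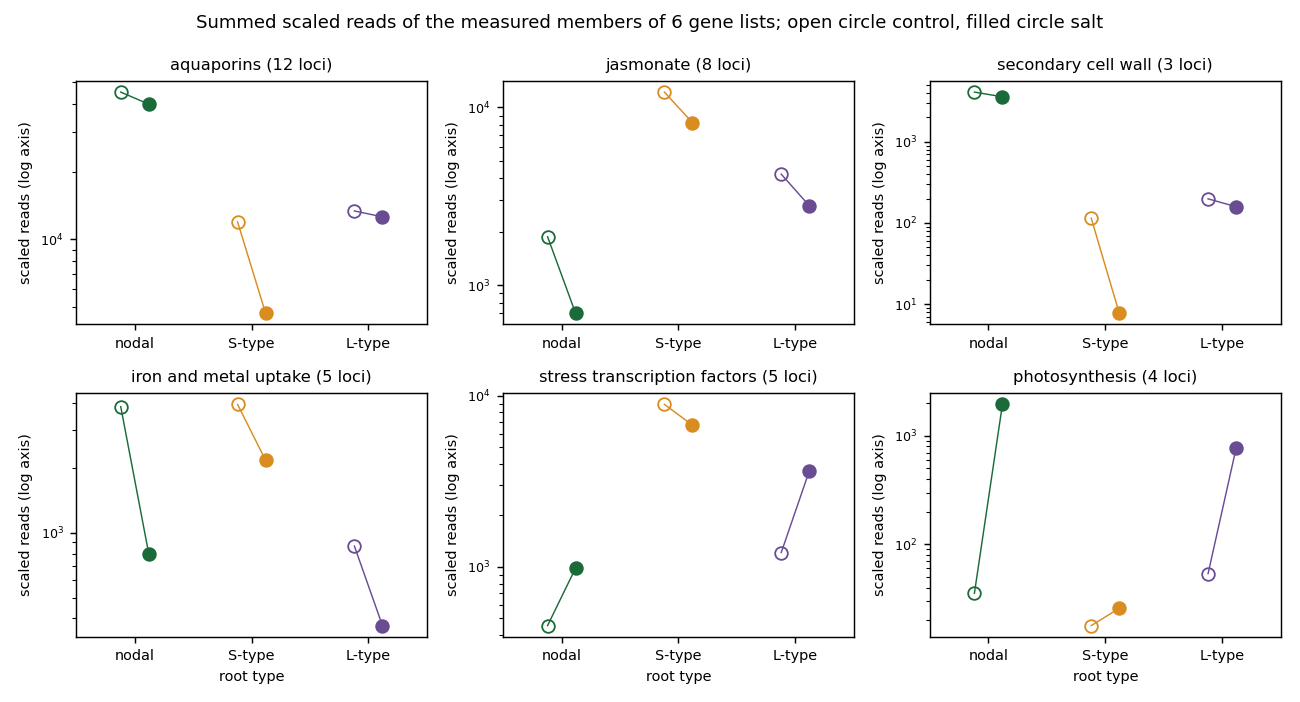
Summed scaled reads of the measured members of 6 gene lists in each library, on log axes that differ between panels; open circles are control, filled circles salt, and lines join libraries of 1 root type. The photosynthesis total was 1942.3 in salt nodal and 766.7 in salt L-type roots and at most 53.8 in the other 4 libraries.

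A change by salt shared by the 3 root types was the question of the additive fit, and limma called 0 loci (2501 at an unadjusted p under 0.05). The edgeR test also called 0 (2126 at an unadjusted p under 0.05) and DESeq2 called 186 higher and 203 lower. Adjusted over the list alone, 4 of 12 aquaporins, 4 of 8 jasmonate loci, 3 of 5 iron and metal uptake loci, 1 of 3 secondary wall loci and 1 of 4 reference genes were lower. Higher by that count were 2 of 3 loci of the Casparian strip list, 2 of 4 photosynthesis loci and 1 iron and metal uptake locus. The 2 of the Casparian strip list were those listed as silicon transporters, while the locus listed for the strip changed by -4.28 in S-type roots. The photosynthesis rise was not shared by S-type roots, where 0 of 4 loci met the rule of size and summed scaled reads were 25.8 under salt. The remaining lists had 0. Without the control S-type library the fit called 791 loci higher and 196 lower, without salt S-type 743 and 177, and without both 213 and 39. By the rule of size, 80 loci were higher and 121 lower under salt in all 3 root types.

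The salt changes of nodal and L-type roots resembled each other more than either resembled those of S-type roots. Across 12229 loci, Pearson's r was 0.505 between nodal and L-type, 0.177 between nodal and S-type and 0.115 between S-type and L-type roots (Spearman's rho 0.444, 0.221 and 0.15); no library is shared within a pair. Nodal and L-type roots had 651 loci higher and 364 lower under salt in both, against 200.0 and 122.2 for independent lists, and 89 loci opposite against 316.9. Nodal and S-type roots shared 106 higher (46.3 for independent lists) and 297 lower (138.1), with 179 opposite (192.6). S-type and L-type roots shared 170 higher (63.2) and 266 lower (136.0), with 256 opposite (246.9). The difference of any 2 salt changes was not tested.

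**Figure D4:**
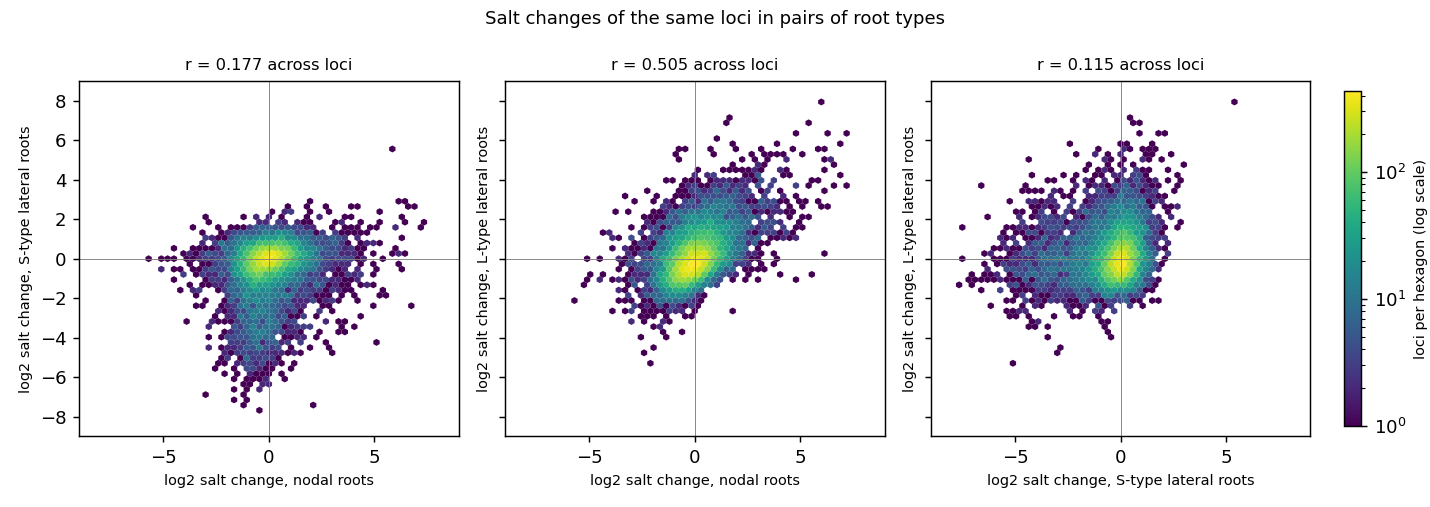
Log2 salt change of 12229 loci in pairs of root types, as hexagons coloured by the number of loci on a log scale; the axes give the salt change of each root type. Nodal and L-type changes follow a common diagonal (r = 0.505), while S-type roots hold a group of loci with large decreases that spreads over both signs of change in the other root types (r = 0.177 and 0.115).

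In the authors' deposited table, Cuffdiff marked 9 loci for salt in nodal roots (8 higher, 1 lower), 23 in S-type roots (1 higher, 22 lower) and 9 in L-type roots (9 higher, 0 lower). Between root types under control, the authors' deposited table marks 85 loci for S-type against nodal roots (40 higher, 45 lower), 30 for L-type against nodal roots (3 higher, 27 lower) and 34 for L-type and S-type roots (30 higher in S-type, 4 lower). Under salt, the authors' deposited table marks 271 (54 higher, 217 lower), 12 (6 higher, 6 lower) and 59 (6 higher in S-type, 53 lower) for the same pairs. The smallest q-value in the authors' deposited table is 0.0144, shared by every comparison.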

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

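The tests of carried-over nodal tissue below were chosen after the result was seen. No group has enough libraries to single out an outlying sample. In pairs of root types, 179 loci met the rule of size in opposite directions under salt between nodal and S-type roots, 256 between S-type and L-type roots and 89 between nodal and L-type roots; with 1 library per group the difference between root types was not tested.

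The S-type salt library is set apart by losses: 1581 loci lower and 624 higher. Scaling does not account for it, since 3 other scalings and thinning to the total reads of the shallowest library left at most 33.0% of the loci higher. Removing a trend on transcript length (from reads per unit of FPKM) left 29.9% higher. A control S-type sample that carried nodal tissue might lose nodal transcripts in this way, but 56.6% of the 1581 lower loci lost more than 0.5 times their control nodal level. The other 686 lost less, so a second test covers them: of 312 loci with at least 1000 scaled reads in both nodal libraries, 12 lay under 0.05 times their control nodal level in the control S-type library. Whole nodal tissue at a share of 0.05 would have lifted these 12. Only 3 of the 1581 lower loci lost so little that a smaller share could account for it. Both tests argue against whole nodal tissue as the cause of the losses as a set. A smaller share might lift the secondary wall loci, with 114.4 summed scaled reads in control S-type and 4107.7 in control nodal roots. Of these 12 loci, Os03g0103200 had 7.1 scaled reads in control S-type and 9993.6 in control nodal roots. Os02g0115700 had 3.6 and 2672.2, and Os01g0881300 had 0 and 1043.1. Each lay at a far smaller share of its control nodal level than the wall loci. Loci nearer the wall loci's share, such as Os02g0662000 (230.0 and 11204.5), set no such limit. The values of the first 3 loci argue against whole nodal tissue for the wall loci too. Tissue from a part of a nodal root that lacks those 12 transcripts was not tested. A response of S-type roots to salt stays open as a hypothesis, as do differences between single samples, which this design gives no means to test.

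Nodal and L-type roots shared much of their salt change (r = 0.505), S-type roots little. Once trends on transcript length and mean level were removed, r was 0.522 between nodal and L-type roots, 0.178 between nodal and S-type and 0.13 between S-type and L-type roots. Photosynthesis loci are nearly off in the control libraries and on in those same salt libraries, so green tissue or another foreign tissue might link them; without the 14 loci under 20 scaled reads in all 3 controls, r was 0.495. That test bears on loci off in controls only. With 14 of 12229 loci removed, r could hardly have fallen, so the test cannot tell whether foreign tissue links these libraries. The photosynthesis signal itself, 1942.3 summed scaled reads in salt nodal and 766.7 in salt L-type roots, was not tested for greening of roots against shoot tissue in the sample. A salt response common to these root types stays open as a hypothesis.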

How the results depend on the processing

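The edgeR test had been set down first as the main test, and its use as an alternative beside limma was chosen after the data were seen. The authors' size factors, thinning, the pseudocount of 10 in the fit, and list medians under median-of-ratios or the authors' factors were also chosen then. Counts from the fits moved most. Where 1 library was left out, the model fits the other library of its root type exactly. The treatment effect and the error then come from the other 2 root types alone, so those counts are not like for like with the fit of all 6 libraries. Salt across the root types: 0 loci by limma, 389 by DESeq2, 252 without both S-type libraries, and 0 to 987 leaving out 1 library. S-type against nodal roots: 3705, with 5991 at a threshold of 0.10 and 389 to 5682 leaving out 1 library. L-type against nodal roots: 0, with 995 by DESeq2, 1074 without both S-type libraries, 89 with a pseudocount of 10, 69 at 0.10 and 0 to 1877 leaving out 1 library. L-type against S-type roots: 2, with 1692 by DESeq2, 1 with no filter, 154 without both nodal libraries, 0 by edgeR, 743 with a pseudocount of 10, 981 at 0.10 and 0 to 2924 leaving out 1 library. Of the other settings, 44 stayed within 1.5 times the reported count.

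Counts by the rule of size moved where the rule itself was loosened or tightened. For salt in nodal, S-type and L-type roots, a minimum of 10 scaled reads gave 5214, 4026 and 6032 loci, a minimum of 200 gave 1412, 867 and 1497, and 4-fold gave 782, 795 and 943. At 4-fold 551 loci were higher and 231 lower in nodal, 53 and 742 in S-type and 788 and 155 in L-type roots. For S-type against nodal, L-type against nodal and L-type against S-type roots under control, a minimum of 200 gave 3429, 2278 and 2089 and 4-fold gave 2841, 1490 and 1743; a minimum of 10 gave 7292 and 7018 for the pairs with L-type roots. Under salt a minimum of 10 gave 9720, 4870 and 7235, a minimum of 200 gave 3316, 1250 and 2151, and 4-fold gave 3715, 957 and 1842. Under other scalings, a pseudocount of 10, FPKM and thinning the counts stayed within 1.5 times, as did the 9087 loci of S-type against nodal roots under control with a minimum of 10. Scaling by library totals turned the majority of loci in S-type against nodal roots under both treatments, L-type against S-type roots under both and L-type against nodal roots under control, with a median log2 shift of all loci from 0.16 to -0.27 for S-type against nodal roots under control.

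With a mean of at least 500 scaled reads, the correlation of salt changes was 0.155 for nodal and S-type, 0.475 for nodal and L-type and 0.185 for S-type and L-type roots; a pseudocount of 10 gave 0.138 for the last pair. The cause was not tested. Of the list medians outside the central 95% of random lists, 1 reversed: sodium and potassium transport in nodal roots, from -1.26 to 0.34 when members needed a mean of 100 scaled reads, which left 3 of the 6 members. Several medians inside that range also changed sign. ABA response in L-type roots went from 0.72 to -0.21 with the same minimum. Nitrate and ammonium transport in S-type against nodal roots went from 0.12 to -1.86 with library totals. Of the other list medians, 8 came to lie inside and 4 outside the central 95% of random lists. For single loci, the 2 calls between L-type and S-type roots were lost in 9 combinations of locus and setting, 30 values of loci moved beyond their counting interval, and no locus reversed. In simulation at the same depth, with the same dispersion for every locus, the salt fit recovered 70% of 2-fold changes at a dispersion of 0.02 and 4% at 0.177. Depth limits ratios that rest on 1 read, as in the counting interval of 89.76 to 19850 at Os05g0111300.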

Other observations

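The test of other splits was chosen after the count of calls was known. Some loci had far apart salt changes in 2 root types, and these differences were not tested. Os06g0666800 (chromosome 6, 27614150 to 27614830) went from 70.1 to 307.4 scaled reads in nodal roots and from 177.5 to 0 in S-type roots. Os07g0498400 (chromosome 7, 18688391 to 18692308) went from 258.5 to 10.3 in S-type and from 7.1 to 109.9 in L-type roots. Os01g0597600 (chromosome 1, 23447172 to 23448687) went from 102.1 to 0.9 in nodal roots and from 459.9 to 477.1 in S-type roots. Each had the largest difference in its direction for a pair of root types, among loci with at least 200 scaled reads in a library; nodal and S-type roots for the first and last, S-type and L-type roots for the other.

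A further question was whether neighbouring loci respond together. A hypothesis is that position on the chromosome may carry part of the salt response. Across 11889 pairs of neighbouring, non-overlapping loci, the correlation of log2 salt changes was 0.062 in nodal, 0.063 in S-type and 0.047 in L-type roots, above the highest of 1000 shuffled orders (0.03, 0.031 and 0.024). The correlation is small. Reads shared between tandem copies might give the same value and were not tested.

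L-type roots lay between nodal and S-type roots on the first principal component. An L-type sample that was a mixture of both tissues might do so. A mixture puts no locus outside the range of its sources, and 0.49% of 12229 loci (60) lay at least 2-fold outside it in the same direction under both treatments, against 0.05% (6.5) for independent lists. Under control alone, 262 loci lay above and 624 below the range, and under salt 134 above and 71 below; the control L-type library lay at -98.3 on the second principal component, with control nodal at -20.4 and control S-type at 4.9. These values go against a mixture of the sampled tissues alone. The share repeated under both treatments is below the 2% set beforehand to exclude a mixture, and with 1 library per group the spread between samples is unknown. A mixture of nodal and S-type tissue that differs from these samples therefore cannot be told apart from an intermediate root type.

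Of the 10 splits of the 6 libraries into 3 and 3, all 10 gave as many loci as the real split, because the real split and the highest of the others both gave 0. With root type in the model, a split that keeps both libraries of 1 root type on the same side reduces to the salt contrast of a single root type, and such splits come in identical pairs, so the 10 splits are not separate tests. With 10 splits a share under 0.05 cannot be reached.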
